A study of Homo sapiens with 77 samples.

How the data were processed

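Total RNA from 77 human muscle samples was hybridised to Affymetrix expression arrays as biotin-labelled cRNA, 1 array per sample, per the labels' protocols. The deposited values are log2 signals per probe set, which the submitters' processing notes credit to GCRMA, a method that corrects background with the probes' base composition, normalizes between arrays and summarises the probes of each probe set. Its version is not given in the sources used here. The lowest value, 2.22, was shared by many probe sets and is the floor that background correction leaves, so fold changes of genes at the floor in a group are understated. Groups were taken from the disease state in the labels: 12 DM, 26 IBM, 12 Normal, 6 NM, 14 NS and 7 PM. Within a group, samples were numbered in the order of deposit, and the numbers pair no samples.

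Of 22283 probe sets, 19071 had 1 gene symbol in the platform annotation, 1043 had several and 2169 were not listed, 62 of them Affymetrix controls. No gene was named from a probe set with several symbols. Of 11963 genes, 4310 had more than 1 probe set, and the probe set with the highest mean over all arrays was taken for the gene. Genes above a log2 value of 4 on at least 6 arrays were kept, which left 7059. Probe sets of near-identical families, such as immunoglobulin chains, HLA chains and myosin heavy chains, may bind related transcripts, so which member a name stands for is uncertain. Some genes were not analysed here.

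All 77 arrays were fitted in 1 linear model with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with a mean for each of the 6 groups. The R package data.table (1.17.8) read the values, and pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 in Python 3.11.15 served for preparation and plots. The 9 comparisons were each of 5 disease groups with Normal, IBM with PM, and DM, IBM and NM each with the unweighted mean of the other 4 disease groups. P-values were adjusted within a comparison by the method of Benjamini and Hochberg, with a threshold of 0.05, and standard errors come from limma's moderated variance. The 5 comparisons with Normal share its 12 arrays, so their chance values are shared too. RNA quality was compared with permutation tests, exact where a group had fewer than 10 arrays and otherwise with 100000 permutations, and all tests were two-sided.

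The samples, comparisons, filter, named-gene rule, alternatives and 31 gene lists (506 members) of pathways and cell type markers were fixed before the data were examined. Each list was tested with camera, which compares a list with all other genes, at a preset correlation between genes of 0.01. Every list was also tested with a correlation estimated from the data and with fry, which asks whether the members move on balance one way. Few list calls held with the estimated correlation. Lists share some members, such as C1QB (macrophage and complement), so their calls are not independent. Members were counted over all genes and, separately, adjusted within the list. The genes named in a comparison with Normal are the 8 largest rises and 4 largest falls past the threshold, and the 3 members with the smallest adjusted p of each of the 4 lists with the smallest camera p. Between disease groups they are the 5 largest rises and 5 largest falls, and 3 members of each of 2 lists. A set of 8 genes fixed beforehand was added, among them KLRG1, CD8A, ISG15, MX1, MYH3 and CHRNA1, wherever measured by a probe set of their own. Where 5 or fewer members of a list passed, some are named outside this rule, and these were chosen after their values were seen.

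The alternatives were no filter, a filter at log2 6, quantile normalization, centring each array on its median, the mean of a gene's probe sets, a variance trend with robust estimation, array weights, RNA quality as a covariate, an added 2-fold threshold, only the compared groups in the fit, and each sample left out in turn. A further 2 were chosen after seeing the data: leaving out the 2 arrays whose median correlation with the others was below 0.9, and leaving out the 9 arrays whose RNA quality difference exceeded 3. A change of sign was counted as a reversal where the value passed the threshold with the fit described above or with the alternative.

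Simulated data took the mean and spread of the 7059 genes, with 50 set to each change. A log2 change of 2 was recovered for 94.0% of genes in DM against Normal, 100% in IBM, 98.0% in NM, 100% in NS and 92.0% in PM. A change of 1 was recovered for 60.0%, 68.0%, 54.0%, 74.0% and 60.0%, and a change of 0.5 for 18.0%, 28.0%, 12.0%, 28.0% and 20.0%, in the same order. False calls made up 2.5%, 7.5%, 2.8%, 3.0% and 1.7% of the genes called.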

Results

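Gene expression was measured in 77 human muscle samples, 1 array each. The submitters present them as biopsies profiled to find genes that differ with diagnosis. The labels place 12 samples in dermatomyositis (DM), an inflammatory disease of skin and muscle, and 26 in inclusion body myositis (IBM), in which lymphocytes surround and enter muscle fibres that also hold protein aggregates. A further 7 came from polymyositis (PM), an inflammation of muscle without the skin disease, 6 from necrotizing myopathy (NM), marked by dying fibres with few lymphocytes, and 14 from myositis that the labels call nonspecific (NS). The remaining 12 were normal muscle (Normal). Nothing in the labels says that the samples of a group came from separate donors, so the p-values measure the spread between these samples. 

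The deposited log2 values ran from a floor of 2.22 to 16.23, and between 24.1% and 33.0% of the probe sets on an array lay at that floor. Pairwise correlations between arrays ranged from 0.827 to 0.994, and no arrays held identical values. RNA quality was read from the log2 signal of the 3′ probe sets of the GAPDH and ACTB controls minus that of their 5′ probe sets, which grows as RNA breaks down. This difference averaged 0.65 ± 0.94 in Normal (SD, n = 12), 0.71 ± 0.48 in DM (n = 12), 1.30 ± 1.19 in IBM (n = 26), 1.24 ± 0.81 in PM (n = 7), 1.82 ± 2.26 in NS (n = 14) and 3.01 ± 3.28 in NM (n = 6). Against Normal, a two-sided exact permutation test gave p = 0.0256 for NM (adjusted p = 0.128 over 5 groups), and a permutation test gave p = 0.0911 for NS (adjusted p = 0.17). The difference exceeded 3 on 9 arrays, of which 2 were NM, 3 NS, 3 IBM and 1 Normal (replicate 11, 3.38). NM replicate 3 (8.21) and NS replicate 13 (8.43) were also the 2 arrays whose median correlation with the others lay below 0.9 (0.849 and 0.876).

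**Figure D1:**
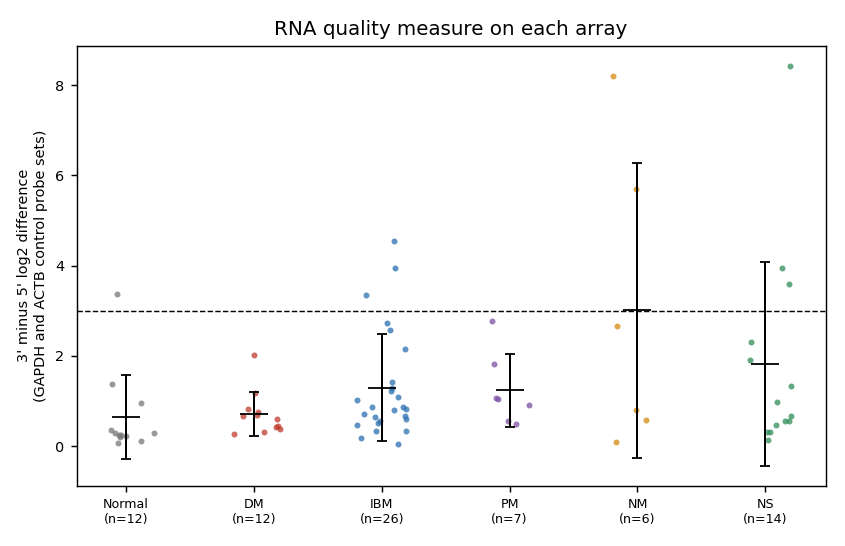
RNA quality of each array, as the log2 difference between 3′ and 5′ control probe sets of GAPDH and ACTB, by group; each point is an array, and the dashed line marks a difference of 3. Of the 9 arrays above the line, 2 are NM, 3 NS, 3 IBM and 1 Normal.

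The comparison of DM with Normal asked which genes differ in dermatomyositis muscle. Genes induced by type I interferon rose furthest: ISG15, a ubiquitin-like protein that interferon induces, was 59.5-fold higher (log2 fold change 5.89, SE 0.61, adjusted p = 6.95e-11, n = 12 and 12), and the antiviral proteins RSAD2 and MX1 were 43.0-fold and 30.5-fold higher. Values in parentheses after gene names are log2 fold changes with their standard error (SE), and every gene said to have risen or fallen had a limma adjusted p below 0.05. List medians are of log2 fold changes, and the adjusted p that follow them are from camera, the one marked as estimated with a correlation estimated from the data. Counts within a list are adjusted over its members alone. IFIT3 (4.81, SE 0.63), the immunoproteasome subunit PSMB8 (4.75, SE 0.76) and the immunoglobulin light chain IGLC1 (4.92, SE 1.02) rose as well. Periostin, a matrix protein encoded by POSTN (4.75, SE 0.91), and the embryonic myosin heavy chain MYH3 (4.63, SE 1.29) were also among the largest rises. The largest falls were in the pseudogene OR7E47P (-2.91, SE 0.49), the phosphoesterase MPPED2 (-2.34, SE 0.51), the secreted protein LGI1 (-2.13, SE 0.41) and the pseudogene NPY6R (-2.08, SE 0.56).

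Of the type I interferon-stimulated genes, 30 of 30 members rose; 30 rose within the list. Their median change was 3.14 (adjusted p = 1.69e-48, 0.0059 estimated), and the list mean was 8.10 ± 2.12 in DM against 4.96 ± 0.27 in Normal (SD), above the highest Normal array in 10 of 12. The membrane protein IFITM1 (2.57, SE 0.33), which restricts virus entry, was among the members with the smallest adjusted p. Of the MHC class I presentation genes, 12 of 14 members rose and 2 did not pass; 12 rose within the list. Among them were the class I heavy chain HLA-B (2.04, SE 0.29) and the peptide transporter TAP1 (3.09, SE 0.45), and the list's median of 1.60 (adjusted p = 1.4e-15, 0.049 estimated) passed both ways. Interferon-gamma-inducible genes showed a median of 1.77 (adjusted p = 1.47e-05, 0.296 estimated), 7 of 11 members rose and 4 did not pass; 8 rose within the list. MHC class II presentation genes had a median change of 0.94 (adjusted p = 0.0416, 0.547 estimated), with 1 of 11 members, HLA-DMA (2.02, SE 0.68), passing, and 2 within the list.

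Among cell type markers, macrophage and monocyte genes showed a median of 1.5 (adjusted p = 2.96e-08, 0.296 estimated). Of 17 members, 7 rose and 10 did not pass; 12 rose within the list. The monocyte receptor CD14 (3.71, SE 0.64) and the complement C1q chains C1QB (4.22, SE 0.74) and C1QA (4.38, SE 0.80) led this list. Plasma cell genes showed a median of 1.52 (adjusted p = 0.00205, 0.375 estimated). Among 10 members, 5 rose and 5 did not pass; 6 rose within the list. CD8A, the coreceptor of cytotoxic T cells, differed by -0.03 (SE 0.37, adjusted p = 0.977). Fibroblast and matrix genes had a median of 0.75 (adjusted p = 0.00166, 0.479 estimated). Of 18 members, 2 rose (POSTN and TNC) and 16 did not pass; 3 rose within the list. Complement genes had a median of 0.65 (adjusted p = 0.00168, 0.322 estimated). Among 14 members, 6 rose and 8 did not pass; 6 rose within the list.

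Genes of regenerating fibres showed a median of 0.95 (adjusted p = 0.017, 0.423 estimated). Of 12 members, 5 rose, 1 fell and 6 did not pass; 6 rose and 1 fell within the list. Denervation-responsive genes showed a median of 0.98 (adjusted p = 0.00816, 0.296 estimated). Among 8 members, 4 rose and 4 did not pass; 4 rose within the list, and the acetylcholine receptor subunit CHRNA1 (3.32, SE 0.59) was 9.98-fold higher. Oxidative phosphorylation genes were lower, with a median of -0.40 (adjusted p = 7.66e-14, 0.296 estimated). Of 37 members, 7 fell and 30 did not pass; 19 fell within the list. The complex I subunit NDUFA1 (-0.54, SE 0.14), the complex IV subunit COX7B (-0.50, SE 0.14) and the complex III subunit UQCRC2 (-0.53, SE 0.16) fell, and the list mean lay below the lowest Normal array in 9 of 12 DM arrays. Fast fibre contractile genes had a median of -0.34 (adjusted p = 0.00181, 0.353 estimated). Among 12 members, 2 fell (CASQ1 and MYH4) and 10 did not pass; 3 fell within the list. Slow fibre contractile genes had a median of -0.29 (adjusted p = 0.00697, 0.375 estimated). Of 10 members, 3 fell (ATP2A2, MYH7 and MYL3) and 7 did not pass; 3 fell within the list. Genes of glycolysis and glycogen use had a median of -0.28 (adjusted p = 0.00166, 0.423 estimated). Among 18 members, 1 fell (PGAM2) and 17 did not pass; 1 fell within the list. Genes of the unfolded protein response had a median of 0.67 (adjusted p = 0.00765, 0.322 estimated). Of 12 members, 5 rose and 7 did not pass; 5 rose within the list. Immediate-early genes had a median of 1.28 (adjusted p = 0.00052, 0.296 estimated). Among 15 members, 7 rose and 8 did not pass; 10 rose within the list.

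Over all 7059 genes, 718 changed in DM, of which 523 rose and 195 fell. The share of higher genes was 72.8%, against 48.7% after quantile normalization and 33.5% after centring each array on its median, which moved the median change of all genes by -0.13 and -0.21. The count was 1904 with array weights and 1199 with only the compared groups in the fit, and centring moved the oxidative phosphorylation median to -0.61 and the fast fibre, slow fibre and glycolysis medians to -0.56, -0.51 and -0.49. Quantile normalization ended the fast fibre (-0.30), slow fibre (-0.22) and glycolysis (-0.29) calls, the fit of the compared groups alone, which leaves fold changes as they are, ended the regeneration and denervation calls, the mean of probe sets ended that of UQCRC2 (-0.59) and moved the plasma cell median to 0.70, and the filters moved the medians of plasma cell (0.47 with none), interferon-gamma (0.99), immediate-early (0.80) and complement genes (1.12 with the stricter one). The MHC class II call ended in 8 of 24 fits without 1 sample (0.67 to 0.93).

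IBM was then compared with Normal. IGLC1 rose furthest, 116-fold (log2 fold change 6.85, SE 0.87, adjusted p = 1.07e-08, n = 26 and 12), followed by MYH3 (86.7-fold) and CXCL9 (79.6-fold), a chemokine that interferon-gamma induces and that attracts T cells. Next came the light chain IGLV1-44 (5.37, SE 0.70), the immunoglobulin joining chain JCHAIN (5.25, SE 0.79), the immunoproteasome subunit PSMB8 (5.07, SE 0.65), the class II chain HLA-DQA1 (4.99, SE 0.80) and the immunoproteasome subunit PSMB9 (4.90, SE 0.55). The largest falls were in the R-spondin receptor LGR5 (-2.53, SE 0.80), the water channel AQP4 (-2.52, SE 0.50), OR7E47P (-2.48, SE 0.42) and MPPED2 (-2.17, SE 0.44).

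Of the MHC class I presentation genes, 12 of 14 members rose and 2 did not pass; 13 rose within the list. The median change was 1.85 (adjusted p = 4.66e-19, 0.0327 estimated), and the list mean lay above the highest Normal array in 25 of 26 arrays (10.26 ± 0.82 against 8.08 ± 0.21, SD). HLA-B and HLA-F rose by 2.31 and 2.78 on the log2 scale. MHC class II presentation genes showed a median of 2.54 (adjusted p = 1.46e-11, 0.0552 estimated). Of 11 members, 10 rose and 1 did not pass; 10 rose within the list. The peptide-loading chain HLA-DMA (4.28, SE 0.58) and the class II chains HLA-DPB1 (2.72, SE 0.38) and HLA-DPA1 (2.79, SE 0.40) led them. Interferon-gamma genes showed a median of 2.67 (adjusted p = 7.53e-11, 0.0552 estimated). Among 11 members, 10 rose and 1 did not pass; 10 rose within the list, led by the guanylate-binding proteins GBP2 (2.82, SE 0.33) and GBP1 (4.66, SE 0.64). Type I interferon-stimulated genes showed a median of 1.17 (adjusted p = 5.48e-07, 0.43 estimated). Of 30 members, 14 rose and 16 did not pass; 17 rose within the list, with ISG15 (2.86, SE 0.52) and MX1 (1.64, SE 0.57) among those that rose.

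T cell genes showed a median of 1.95 (adjusted p = 8.79e-05, 0.165 estimated). Among 6 members, 5 rose and 1 did not pass; 5 rose within the list. Cytotoxic effector genes showed a median of 1.34 (adjusted p = 2.16e-06, 0.205 estimated). Of 14 members, 9 rose and 5 did not pass; 11 rose within the list, with CD8A (1.48, SE 0.31) among those that rose. KLRG1, a receptor of late-stage cytotoxic T cells, lay near the floor and was left out by the filter. Its mean was 2.28 ± 0.19 in IBM and 2.22 ± 0.01 in Normal (SD), with an adjusted p of 0.461 when no filter was applied. Plasma cell genes showed a median of 2.54 (adjusted p = 4.15e-09, 0.0683 estimated). Among 10 members, 9 rose and 1 did not pass; 9 rose within the list. Macrophage genes showed a median of 1.96 (adjusted p = 1e-12, 0.101 estimated). Of 17 members, 14 rose and 3 did not pass; 15 rose within the list, with CD14 (3.93, SE 0.55), lysozyme, encoded by LYZ (3.81, SE 0.57), and C1QB (4.25, SE 0.63) at their head.

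Genes of regenerating fibres had a median of 0.83 (adjusted p = 0.0029, 0.404 estimated). Among 12 members, 5 rose, 1 fell (CDKN1C) and 6 did not pass; 6 rose and 1 fell within the list. Denervation genes had a median of 0.70 (adjusted p = 0.0296, 0.404 estimated). Of 8 members, 5 did not pass and 3 rose (3 within the list): CHRNA1 (12.4-fold), GADD45A and NCAM1. Fibroblast and matrix genes had a median of 1.01 (adjusted p = 2.39e-05, 0.43 estimated). Among 18 members, 11 rose and 7 did not pass; 13 rose within the list. Complement genes had a median of 0.91 (adjusted p = 9.05e-05, 0.205 estimated). Of 14 members, 7 rose and 7 did not pass; 9 rose within the list. Oxidative phosphorylation genes had a median of -0.22 (adjusted p = 9.9e-06, 0.54 estimated), with 1 of 37 members passing, UQCRC2 (-0.36, SE 0.13), and 0 within the list. Genes of glycolysis had a median of -0.20 (adjusted p = 0.0166, 0.627 estimated), and 0 of 18 passed in either adjustment. Of 13 proteins reported in IBM aggregates, 4 rose (4 within the list) and 9 did not pass. Those that rose were the chaperone clusterin, encoded by CLU (1.25, SE 0.39), the amyloid-processing protease BACE1 (0.72, SE 0.25), the prion protein gene PRNP (0.63, SE 0.22) and the RNA-binding protein gene TARDBP (0.51, SE 0.18). The list as a whole did not pass (median -0.03, adjusted p = 0.68, 0.833 estimated). Its mean was 10.51 ± 0.23 against 10.26 ± 0.17 in Normal (SD), above the highest Normal array in 19 of 26. It was 10.51 ± 0.22 in PM and 10.47 ± 0.27 in DM.

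In all, 1406 genes changed in IBM, 1009 upward and 397 downward, so that 71.8% were higher, against 58.4% after quantile normalization and 35.7% after median centring, which moved the median change of all genes by -0.20. The count was 2130 with median centring and 2745 with array weights, and centring moved the oxidative phosphorylation median to -0.43 and the glycolysis median to -0.41. The glycolysis call ended with quantile normalization (-0.15) and with RNA quality as a covariate (-0.10), the denervation call with array weights (0.60), which also moved the oxidative phosphorylation median to -0.13, and the MX1 call with quantile normalization (1.49), with no filter or without Normal replicate 3, 8, 10 or 12 (1.53 to 1.57). Members near the floor brought the unfiltered medians of T cell, cytotoxic, plasma cell and denervation genes to 0.27, 0.19, 1.31 and 0.39, and the mean of probe sets that of plasma cell genes to 1.53.

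PM was compared with Normal in the same way. Embryonic myosin MYH3 (91.8-fold, log2 fold change 6.52, SE 1.5, adjusted p = 0.00165, n = 7 and 12) and CXCL9 (78.9-fold) rose furthest. IGLC1 (5.62, SE 1.18), the interferon-gamma-induced chemokine CXCL10 (46.8-fold), PSMB8 (5.37, SE 0.88), GBP1 (5.25, SE 0.87), the muscle protein MYBPH (5.05, SE 1.13) and C1QA (4.95, SE 0.93) completed the largest rises. Falls were largest for AQP4 (-3.21, SE 0.68), OR7E47P (-2.82, SE 0.58), the calcium channel subunit CACNA2D1 (-2.67, SE 0.67) and NPY6R (-2.63, SE 0.66).

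MHC class I presentation genes showed a median of 1.98 (adjusted p = 4.08e-16, 0.0767 estimated). Among 14 members, 12 rose and 2 did not pass; 12 rose within the list, with HLA-B (2.32, SE 0.34), HLA-F (2.91, SE 0.43) and TAP1 (3.53, SE 0.53) leading. MHC class II presentation genes had a median of 2.44 (adjusted p = 3.1e-08, 0.134 estimated). Of 11 members, 10 rose and 1 did not pass; 10 rose within the list. Interferon-gamma genes had a median of 2.77 (adjusted p = 3.9e-09, 0.134 estimated). Among 11 members, 8 rose and 3 did not pass; 8 rose within the list. Type I interferon-stimulated genes had a median of 1.67 (adjusted p = 7.31e-12, 0.276 estimated). Of 30 members, 17 rose and 13 did not pass; 22 rose within the list. ISG15 was 17.7-fold and MX1 10.9-fold higher, and IFI27 (2.87, SE 0.54) and IFITM1 (1.97, SE 0.39) rose too. The type I list mean lay above the highest Normal array in 7 of 7 PM arrays. Macrophage genes showed a median of 2.57 (adjusted p = 2.36e-13, 0.134 estimated). Among 17 members, 15 rose and 2 did not pass; 17 rose within the list, including CD14 (4.08, SE 0.74) and C1QB (4.57, SE 0.86). T cell genes had a median of 1.84 (adjusted p = 0.00398, 0.276 estimated). Of 6 members, 5 rose and 1 did not pass; 5 rose within the list. Cytotoxic effector genes had a median of 1.20 (adjusted p = 0.000114, 0.276 estimated). Among 14 members, 6 rose and 8 did not pass; 12 rose within the list. CD8A itself did not pass (1.16, SE 0.43, adjusted p = 0.064), but did with array weights (1.52), with only the compared groups in the fit and without PM replicate 2, 6 or 7 (1.31 to 1.45). Plasma cell genes had a median of 2.29 (adjusted p = 5.9e-05, 0.276 estimated). Of 10 members, 5 rose and 5 did not pass; 8 rose within the list.

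Genes of regenerating fibres had a median of 1.12 (adjusted p = 0.0065, 0.369 estimated). Among 12 members, 5 rose and 7 did not pass; 7 rose within the list. Denervation genes had a median of 1.05 (adjusted p = 0.0174, 0.276 estimated). Of 8 members, 3 rose (CHRNA1, GADD45A and MYOG) and 5 did not pass; 4 rose within the list. CHRNA1 was 15.4-fold higher. Fibroblast and matrix genes had a median of 0.87 (adjusted p = 0.00645, 0.558 estimated). Among 18 members, 3 rose (FN1, POSTN and TNC) and 15 did not pass; 5 rose within the list. Complement genes had a median of 1.30 (adjusted p = 0.00101, 0.276 estimated). Of 14 members, 7 rose and 7 did not pass; 9 rose and 1 fell within the list. Immediate-early genes had a median of 1.48 (adjusted p = 0.00509, 0.276 estimated). Among 15 members, 5 rose and 10 did not pass; 9 rose within the list. Oxidative phosphorylation genes had a median of -0.36 (adjusted p = 1.06e-10, 0.276 estimated), where 2 of 37 fell, the complex IV subunit COX5B (-0.49, SE 0.16) and the complex I subunit NDUFA8 (-0.78, SE 0.27), and 0 passed within the list. Genes of glycolysis had a median of -0.30 (adjusted p = 0.00101, 0.385 estimated), and 0 of 18 passed in either adjustment.

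Of all genes, 859 changed in PM, with 742 higher and 117 lower. That is 86.4% higher, against 65.9% after quantile normalization and 39.3% after median centring, with shifts of the median of all genes by -0.15 and -0.29. The count was 515 without PM replicate 4, 1294 with median centring, 2235 with array weights and 1434 with only the compared groups, which ended the denervation call, and centring moved the medians of matrix, oxidative phosphorylation and glycolysis genes to 0.58, -0.65 and -0.59. Without the filter, the medians of T cell, cytotoxic, plasma cell and denervation genes were 0.21, 0.39, 0.96 and 0.45, the mean of probe sets gave 1.16 for plasma cell genes and ended the call of COX5B (-0.49), and that of NDUFA8 ended without the filter or with RNA quality as a covariate (-0.74). Of the 19 fits without 1 sample, 5 ended the call of COX5B (-0.49 to -0.34, PM replicates 1, 2, 4 and 5 and Normal replicate 8) and 13 that of NDUFA8 (-0.79 to -0.62), and the denervation call ended without PM replicate 5 (0.94).

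**Figure D2:**
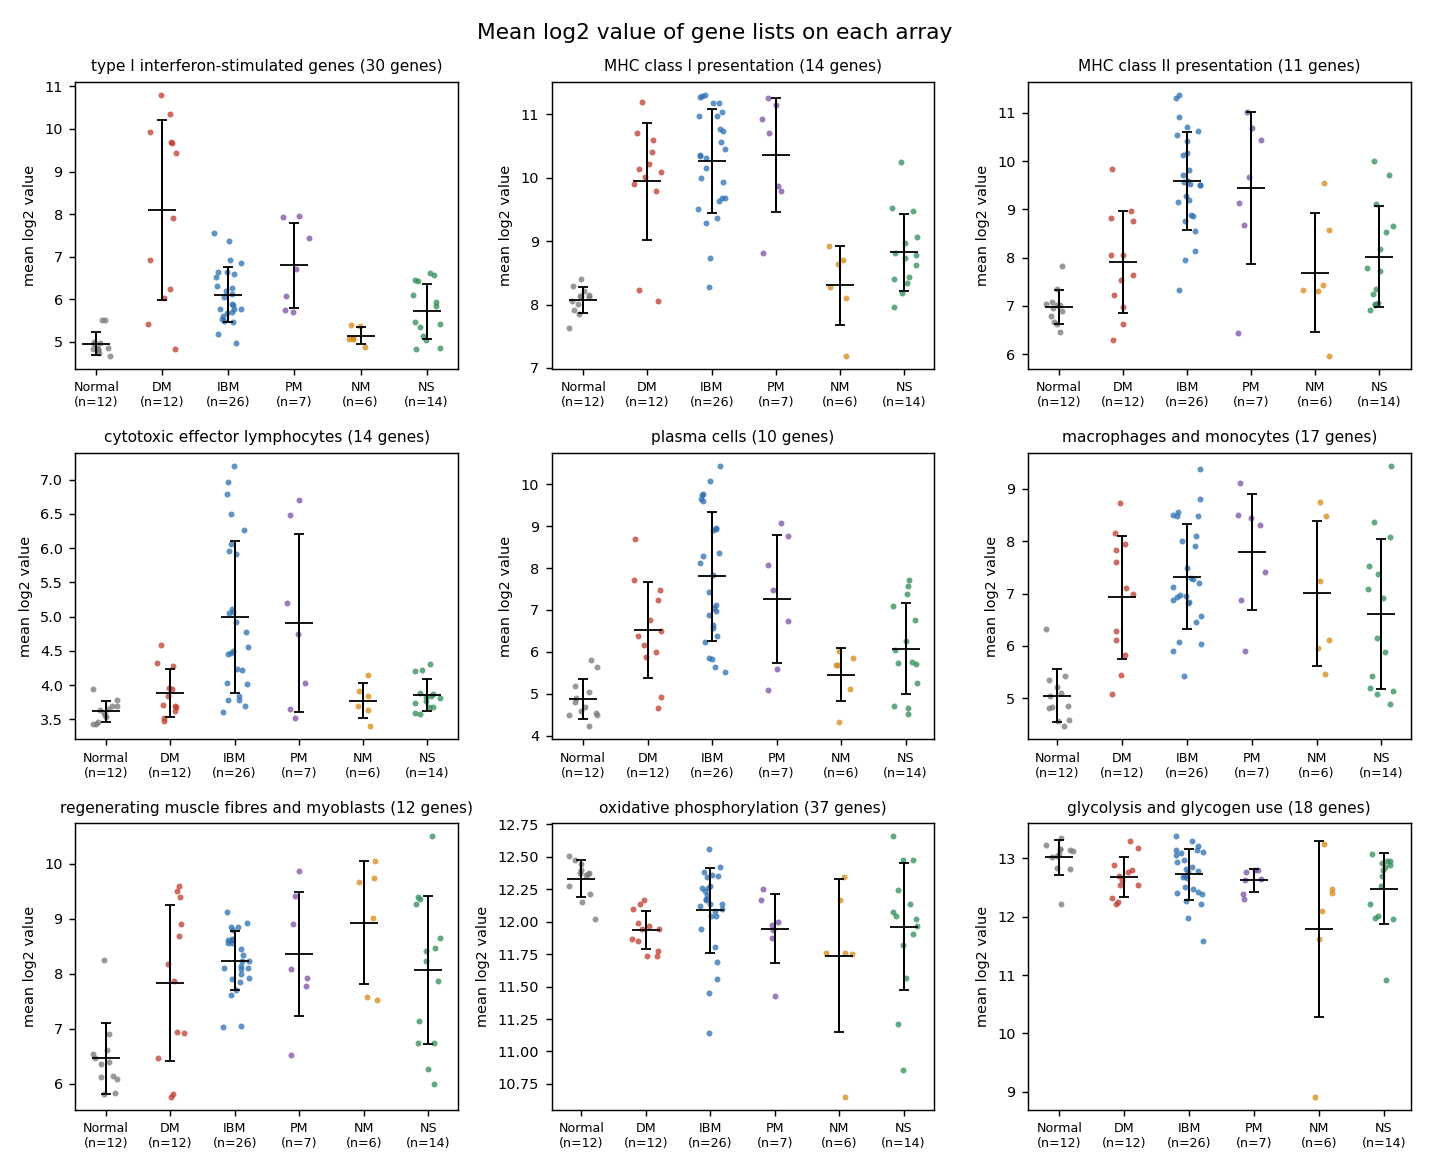
Mean log2 value of the tested members of 9 gene lists on each array (points), by group, with the group mean and SD (bars). The type I interferon list averages 8.10 ± 2.12 in DM, 6.80 ± 0.99 in PM and 4.96 ± 0.27 in Normal, and the cytotoxic list 4.99 ± 1.11 in IBM, 4.90 ± 1.30 in PM and 3.88 ± 0.35 in DM.

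NM was compared with Normal likewise. MYH3 rose furthest, 311-fold (log2 fold change 8.28, SE 1.58, adjusted p = 0.000353, n = 6 and 12), followed by POSTN (5.59, SE 1.11), MYBPH (5.10, SE 1.19), the cell cycle inhibitor CDKN1A (4.82, SE 0.57), PRUNE2 (4.80, SE 0.94), the perinatal myosin MYH8 (4.69, SE 0.95), tenascin C, a matrix protein encoded by TNC (4.65, SE 0.97), and MLLT11 (4.13, SE 0.78). The largest falls were in the tetraspanin TSPAN8 (-4.44, SE 0.81), LGR5 (-4.13, SE 1.14), the muscle fructose bisphosphatase FBP2 (-3.86, SE 0.70) and AQP4 (-3.72, SE 0.71). Of the interferon genes fixed in advance, ISG15 (1.55, SE 0.75, adjusted p = 0.126) and MX1 (0.28, SE 0.82, adjusted p = 0.842) did not pass, nor did CD8A (0.16, SE 0.45). ISG15 passed with array weights (2.05) and with only the compared groups in the fit.

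Genes of regenerating fibres showed a median of 1.66 (adjusted p = 1.7e-05, 0.547 estimated). Of 12 members, 7 rose and 5 did not pass; 7 rose and 1 fell within the list. Denervation genes had a median of 0.83 (adjusted p = 0.0411, 0.547 estimated). Among 8 members, 4 did not pass and 4 rose (4 within the list): CHRNA1 (3.70, SE 0.72), GADD45A, MYOG and NCAM1. Macrophage genes showed a median of 1.89 (adjusted p = 9.95e-07, 0.547 estimated). Of 17 members, 9 rose and 8 did not pass; 14 rose within the list, with CD14 (3.89, SE 0.78), the adaptor TYROBP (2.80, SE 0.69) and the macrophage complement receptor VSIG4 (2.85, SE 0.74) first. Fibroblast and matrix genes showed a median of 1.56 (adjusted p = 1.08e-06, 0.547 estimated). Among 18 members, 10 rose and 8 did not pass; 14 rose within the list, including SPARC (1.45, SE 0.35). Complement genes had a median of 0.98 (adjusted p = 0.0145, 0.579 estimated). Of 14 members, 7 rose, 1 fell (CD59) and 6 did not pass; 8 rose and 2 fell within the list. The RNA quality difference of 3.01 ± 3.28 in NM against 0.65 ± 0.94 in Normal (SD) stands beside these. Without the 9 arrays above the RNA quality limit, the medians were 2.07 for regeneration, 1.07 for denervation, 2.52 for macrophage, 1.88 for matrix and 1.12 for complement genes.

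Of the genes of glycolysis, 14 of 18 members fell and 4 did not pass, and 14 fell within the list, with a median of -1.20 (adjusted p = 2.32e-07, 0.547 estimated). Muscle glycogen phosphorylase, encoded by PYGM (-3.08, SE 0.60), its activating kinase subunit PHKA1 (-1.96, SE 0.46) and the muscle phosphoglycerate mutase PGAM2 (-1.71, SE 0.42) led them. Oxidative phosphorylation genes showed a median of -0.48 (adjusted p = 1.15e-07, 0.578 estimated). Among 37 members, 16 fell and 21 did not pass; 20 fell within the list, with NDUFV2 (-1.47, SE 0.30), COX6A2 (-1.55, SE 0.32) and SDHD (-0.90, SE 0.25) first. Fast fibre contractile genes had a median of -0.71 (adjusted p = 0.0251, 0.627 estimated). Of 12 members, 3 fell (ATP2A1, MYBPC2 and TNNI2) and 9 did not pass; 3 fell within the list. Without the arrays above the RNA quality limit (mean difference 3.01 in NM against 0.65 in Normal with all arrays), the medians were -0.34 for glycolysis, -0.35 for oxidative phosphorylation and -0.10 for fast fibre genes, where the last was no longer called, and PGAM2 (-1.14), SDHD (-0.51) and LGR5 (-3.78) lost their calls. Without NM replicate 3, NDUFV2, COX6A2 and PYGM were at -0.93, -0.80 and -1.62, the glycolysis median was -0.51 and the fast fibre call ended (-0.26), as it did without NM replicate 1 (-0.63).

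Of all genes, 1478 changed in NM, 680 upward and 798 downward. The share of higher genes was 46.0%, against 62.9% without the filter, 54.3% after quantile normalization and 62.3% with array weights. Without the arrays above the RNA quality limit, 846 changed, 626 upward and 220 downward, of which 662 were among the 1478. The count was 889 without NM replicate 4 and 603 with RNA quality as a covariate, which ended the calls of PGAM2 (-1.10) and SDHD (-0.59) and moved the glycolysis median to -0.52, the fast fibre median to -0.47 and the denervation median to 1.36, and array weights and the absence of NM replicate 3 and NS replicate 13 moved the glycolysis median to -0.53 and -0.51. The fast fibre call ended in these last fits (-0.45 and -0.26), with the stricter filter and with only the compared groups, the complement call with no filter (0.84) or the stricter one (0.72), and the denervation call with no filter (0.28), quantile normalization (0.76) or only the compared groups, while quantile normalization moved the oxidative phosphorylation median to -0.30. The denervation call also ended without NM replicate 1 (0.56), 2 (0.85) or 5 (0.87), and the complement median was 0.59 without NM replicate 4.

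NS was compared with Normal likewise. MYH3 (50.2-fold, log2 fold change 5.65, SE 1.24, adjusted p = 0.00299, n = 14 and 12) rose furthest, followed by POSTN (3.86, SE 0.88), CDKN1A (3.79, SE 0.45), MYH8 (3.60, SE 0.75), IGLC1 (3.59, SE 0.98), PRUNE2 (3.52, SE 0.74), MYBPH (3.40, SE 0.93) and CHRNA1 (3.13, SE 0.56). Falls were largest for the kinase HIPK3 (-3.08, SE 0.83), AQP4 (-3.08, SE 0.56), LGR5 (-3.03, SE 0.90) and NPY6R (-2.70, SE 0.54). ISG15 (2.24, SE 0.59) rose, while MX1 (1.75, SE 0.64, adjusted p = 0.0627) and CD8A (0.18, SE 0.35, adjusted p = 0.778) did not pass, although MX1 did after median centring, with only the compared groups in the fit and without Normal replicate 11 or NS replicate 1, 3 or 14.

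Macrophage genes showed a median of 1.52 (adjusted p = 3.05e-08, 0.42 estimated). Among 17 members, 10 rose and 7 did not pass; 11 rose within the list, with CD14 (2.83, SE 0.62), TYROBP (2.18, SE 0.54) and VSIG4 (2.34, SE 0.58) first. Genes of regenerating fibres showed a median of 0.84 (adjusted p = 0.000154, 0.42 estimated). Of 12 members, 4 rose and 8 did not pass; 7 rose and 1 fell within the list, including the developmental actin ACTC1 (2.31, SE 0.54). Type I interferon-stimulated genes had a median of 0.68 (adjusted p = 4.13e-05, 0.444 estimated). Among 30 members, 26 did not pass and 4 rose (7 within the list): IFITM1 (1.44, SE 0.32), IFITM3 (1.0, SE 0.24), ISG15 and SIGLEC1. MHC class I presentation genes had a median of 0.68 (adjusted p = 0.000206, 0.42 estimated). Of 14 members, 5 rose and 9 did not pass; 7 rose within the list. MHC class II presentation genes had a median of 1.0 (adjusted p = 0.000575, 0.42 estimated). Among 11 members, 2 rose (HLA-DMB and HLA-DPB1) and 9 did not pass; 7 rose within the list. Interferon-gamma genes had a median of 0.69 (adjusted p = 0.00276, 0.42 estimated). Of 11 members, 2 rose (GBP2 and IRF8) and 9 did not pass; 4 rose within the list. Plasma cell genes had a median of 0.97 (adjusted p = 0.00449, 0.42 estimated). Among 10 members, 3 rose (FKBP11, IGKC and IGLC1) and 7 did not pass; 3 rose within the list. The RNA quality difference was 1.82 ± 2.26 in NS and 0.65 ± 0.94 in Normal (SD), and without the arrays above its limit the medians of these lists were 1.40, 0.99, 0.58, 0.59, 0.82, 0.37 and 0.62 in the order given, with the calls of the last pair and of IGLC1 (2.88) lost.

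Fibroblast and matrix genes had a median of 0.70 (adjusted p = 0.000224, 0.42 estimated). Of 18 members, 3 rose (COL6A3, POSTN and TNC) and 15 did not pass; 5 rose within the list. Smooth muscle and pericyte genes had a median of 0.43 (adjusted p = 0.028, 0.42 estimated). Among 9 members, 1 rose (MCAM) and 8 did not pass; 1 rose within the list. Complement genes had a median of 0.81 (adjusted p = 0.00172, 0.42 estimated). Of 14 members, 4 rose (C1QB, C1R, C1S and C3) and 10 did not pass; 4 rose within the list. Immediate-early genes had a median of 0.59 (adjusted p = 0.0416, 0.42 estimated). Among 15 members, 1 rose (MYC) and 14 did not pass; 2 rose within the list. Oxidative phosphorylation genes showed a median of -0.37 (adjusted p = 4.57e-07, 0.42 estimated). Of 37 members, 4 fell and 33 did not pass; 10 fell within the list. Those that fell included SDHD (-0.68, SE 0.20), UQCRB (-0.37, SE 0.13) and UQCRC2 (-0.45, SE 0.15). Genes of glycolysis had a median of -0.41 (adjusted p = 0.00172, 0.42 estimated). Among 18 members, 1 fell (PGAM2) and 17 did not pass; 1 fell within the list. Beside these groups too stands the RNA quality difference of 1.82 in NS against 0.65 in Normal, and without the arrays above its limit the medians in the order given were 0.76, 0.55, 0.74, 0.58, -0.36 and -0.31.

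In NS, 755 genes changed, with 338 higher and 417 lower (44.8% higher, against 54.5% after quantile normalization and 62.3% with RNA quality as a covariate), and 573 changed without the arrays above the RNA quality limit, of which 486 were among the 755. The count was 403, 463 and 503 without NS replicates 10, 11 and 13, 430 with RNA quality as a covariate, which ended the glycolysis call (-0.19), and 385 with only the compared groups, which ended the calls of MYBPH and SDHD. The calls of LGR5 (-2.76) and SDHD (-0.54) ended without NS replicate 10. Those of UQCRB and UQCRC2 ended under most alternatives and in 14 of 26 fits without 1 sample each, with UQCRC2 at -0.25 with array weights. Array weights also gave medians of 0.39, 0.60, -0.16 and -0.26 for interferon-gamma, plasma cell (no longer called), oxidative phosphorylation and glycolysis genes. The mean of probe sets gave 0.46 for plasma cell and 0.22 for smooth muscle genes, quantile normalization -0.22 for oxidative phosphorylation, and the filters 0.42 for plasma cell, 1.22 for interferon-gamma and 0.54 for immediate-early genes, which lost their call. That call ended in 10 of 26 fits without 1 sample (0.47 to 0.68) and the smooth muscle call in 3 (0.37 to 0.44), and the interferon-gamma median was 0.43 without NS replicate 12.

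By camera with the preset correlation, 12 of the 31 lists changed in none of the 5 comparisons with Normal. Their lowest and highest medians there, with the lowest camera adjusted p, were as follows. Among immune and blood cells these were naive and central memory T cell genes (-0.02 to 0.14, 0.433), dendritic cell genes (0.00 to 0.34, 0.218), mast cell genes (0.01 to 0.54, 0.0908) and erythroid genes (-0.71 to 0.49, 0.0639). B cell genes were represented by 1 tested member and ran from -0.03 to 0.58 (lowest camera adjusted p = 0.558). Among other cell types these were endothelial genes (-0.11 to 0.12, 0.226), adipocyte genes (-0.19 to 0.39, 0.169) and Schwann cell genes (-0.04 to 0.41, 0.218). Among pathways these were ubiquitin and autophagy genes (-0.24 to 0.00, 0.158), proteins of IBM aggregates (-0.03 to 0.24, 0.68), sterol synthesis genes (-0.58 to 0.05, 0.114) and cell cycle genes (0.18 to 0.28, 0.218). Fry did call mast cell genes in IBM (median 0.46, fry adjusted p = 0.013, 3 of 4 members higher within the list) and PM (0.54, 0.0209) and sterol synthesis genes in NM (-0.58, 0.00928). Camera calls were gained for mast cell genes in PM without the filter (0.45) and with array weights (0.68), erythroid genes in PM with the stricter filter (-1.52) and with RNA quality as a covariate (-0.80), endothelial genes in NS with array weights (0.34) and cell cycle genes in NS without the filter (0.18).

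**Figure D3:**
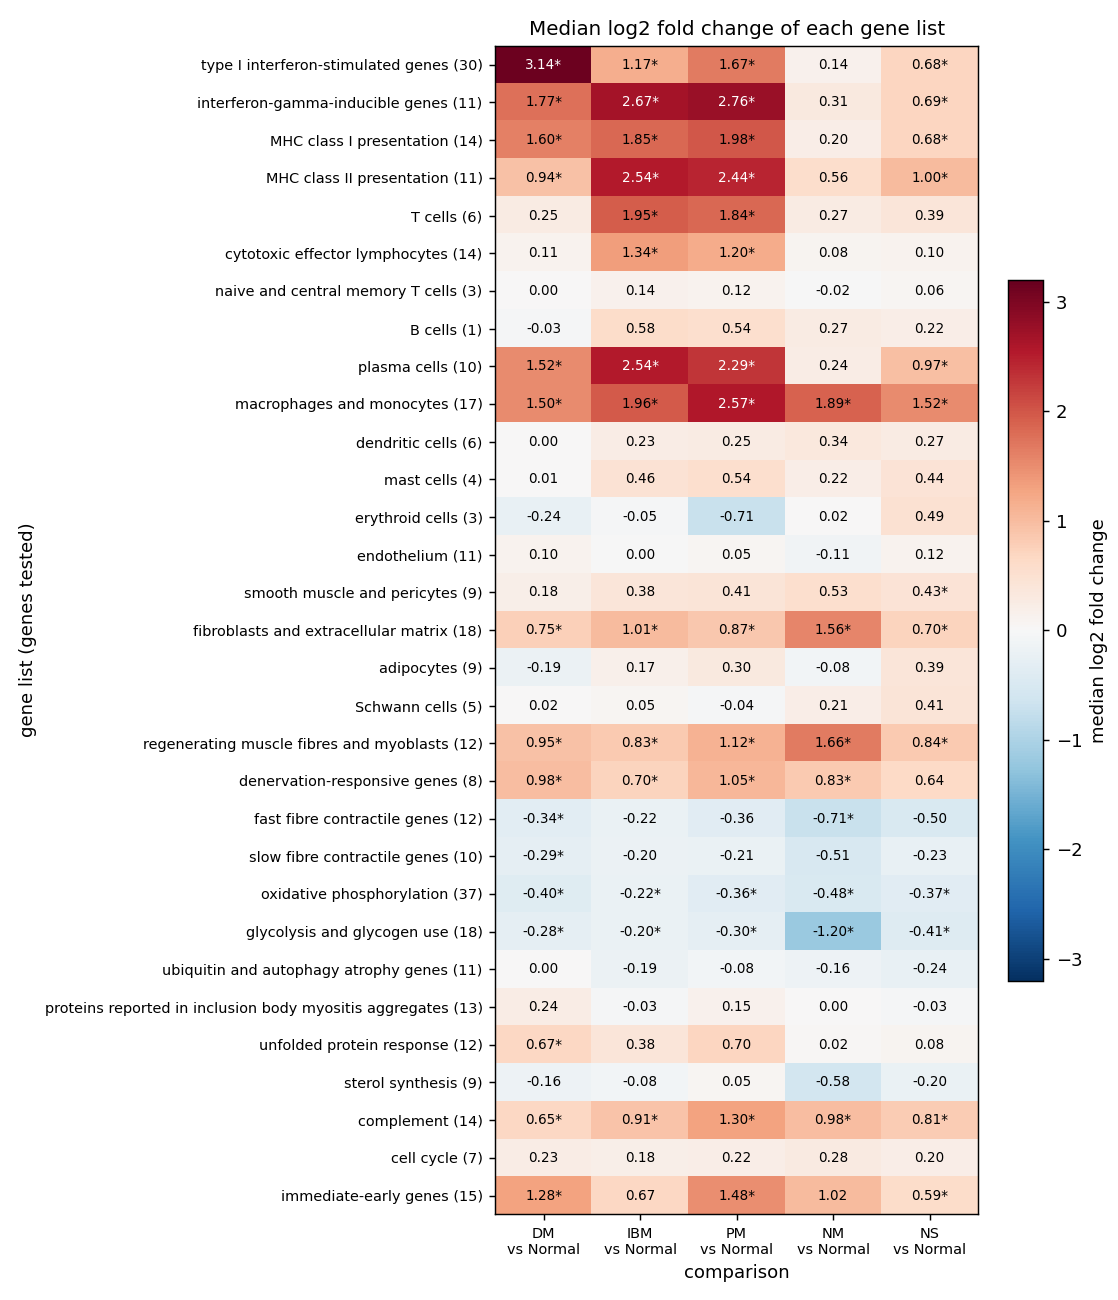
Median log2 fold change of each of the 31 gene lists (vertical axis, with the number of genes tested) in the 5 comparisons with Normal (horizontal axis); colour and number give the median, and an asterisk marks a camera adjusted p below 0.05 with the preset correlation of 0.01. The type I interferon list reads 3.14 in DM and 0.14 in NM, and the T cell list 1.95 in IBM, 1.84 in PM and 0.25 in DM.

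IBM was also compared directly with PM. Of 7059 genes, limma called 0 as different (n = 26 and 7), with 193 at an unadjusted p under 0.05. CD8A differed by 0.32 (SE 0.38), MX1 by -1.80 (SE 0.69), ISG15 by -1.28 (SE 0.64), MYH3 by -0.08 (SE 1.34) and CHRNA1 by -0.30 (SE 0.61), each with an adjusted p of 0.999. At the level of lists, type I interferon-stimulated genes had a lower median in IBM (-0.63, adjusted p = 9.92e-09, 0.855 estimated), as did immediate-early genes (-0.69, adjusted p = 7.46e-07, 0.0744 estimated). Medians were higher in IBM for erythroid (0.67, adjusted p = 0.000183, 0.0724 estimated), plasma cell (0.42, adjusted p = 0.0077, 0.901 estimated) and oxidative phosphorylation genes (0.14, adjusted p = 9.92e-09, 0.855 estimated).

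The same held for fast fibre genes (0.14, adjusted p = 0.0193, 0.901 estimated) and genes of glycolysis (0.08, adjusted p = 0.0161, 0.901 estimated). Within the lists, 1 erythroid member was higher and 1 immediate-early member lower in IBM, and no others passed. None of the 31 lists differed by fry or with an estimated correlation. In other fits the count was 1 with array weights, 3 with only IBM and PM in the fit, and 1 each without PM replicates 1, 4 and 5. The fast fibre call ended after quantile normalization (0.16), after median centring (0.23) and with array weights (0.09), the glycolysis call after quantile normalization, and the plasma cell call after centring (0.50) and with array weights (0.27). The mean of probe sets gave 0.26 for plasma cell genes. Centring gave 0.23 for oxidative phosphorylation and 0.17 for glycolysis genes, and the erythroid median was 0.15 without the filter and 1.32 with the stricter one. Macrophage genes (-0.32, not called) were called lower in IBM under 4 alternatives. Without single PM samples the erythroid median was 0.38 (replicate 1), 0.62 (replicate 5, adjusted p = 0.0327) and 1.03 (replicate 7). The mean of these genes differed between IBM and PM by 0.91 (SE 0.59) and by 0.46 (SE 0.44) without replicate 5, the lowest of PM. The plasma cell call ended without PM replicate 5 (0.06), 6 (0.08) or 7 (0.48), with 0.68 without replicate 1 or 3, the glycolysis call in 3 of 33 fits without 1 sample (0.04 to 0.09) and the fast fibre call in 5 (0.07 to 0.13). Fast fibre genes were at 0.29 and 0.22 without PM replicate 5 and IBM replicate 11, glycolysis genes at 0.13 without IBM replicate 6 and oxidative phosphorylation genes at 0.05 without PM replicate 4.

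Each of DM, IBM and NM was also set against the mean of the other 4 disease groups, any of which may still match it. In DM, type I interferon genes stood out: RSAD2 was 17.2-fold higher than in the other diseases (log2 fold change 4.10, SE 0.65, adjusted p = 1.72e-05, n = 12 DM arrays), and ISG15 (3.19, SE 0.50), MX1 (3.16, SE 0.54), the oligoadenylate synthetase OAS1 (3.01, SE 0.44) and IFIT3 (2.96, SE 0.51) followed. Of the type I list, 26 of 30 members rose and 4 did not pass, and 28 rose within the list, with a median of 2.10 (adjusted p = 9.8e-51, 0.00431 estimated). OAS3 (2.54, SE 0.34), the ISG15 protease USP18 (2.86, SE 0.40) and the ISG15 ligase HERC5 (2.82, SE 0.41) had the smallest adjusted p. The largest falls were in MYH8 (-2.27, SE 0.63), the myosin light chain MYL5 (-2.25, SE 0.55), the microtubule protein MAP1A (-1.99, SE 0.42), the inhibitory Fc receptor FCGR2B (-1.48, SE 0.34) and AGMAT (-1.43, SE 0.37).

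MHC class II presentation genes were lower in DM than in the other diseases (median -0.72, adjusted p = 0.000101, 0.369 estimated), where 1 of 11 members fell and 10 did not pass; 2 fell within the list. The member that fell was HLA-DPB1 (-1.32, SE 0.36). T cell (-0.90, adjusted p = 0.00597, 0.369 estimated), cytotoxic (-0.47, adjusted p = 0.00114, 0.523 estimated) and macrophage genes (-0.38, adjusted p = 0.043, 0.684 estimated) had lower medians. Lower medians were also found for dendritic cell (-0.45, adjusted p = 0.00683, 0.285 estimated), mast cell (-0.38, adjusted p = 0.0293, 0.369 estimated) and regeneration genes (-0.30, adjusted p = 0.0252, 0.565 estimated). MHC class I presentation (0.52, adjusted p = 0.00683, 0.565 estimated) and unfolded protein response genes (0.47, adjusted p = 0.00724, 0.369 estimated) had higher ones. The class I mean was still lower in DM (9.94) than in IBM (10.26) and PM (10.36). Those past the threshold were 0 of 6 T cell members, 0 of 14 cytotoxic members, 1 of 17 macrophage members (FCGR2B), 0 of 6 dendritic cell members, 0 of 4 mast cell members, 2 of 12 regeneration members (MYH8 and MYL4), 0 of 14 MHC class I members and 1 of 12 unfolded protein response members (ASNS). Adjusted over the list alone they numbered 3, 0, 1, 1, 0, 2, 2 and 4. CD8A (-0.77, SE 0.30, adjusted p = 0.168), MYH3 (-2.09, SE 1.04) and CHRNA1 (-0.28, SE 0.48) did not pass.

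In total 97 genes changed, 75 upward and 22 downward (77.3% higher, against 51.5% after quantile normalization, which moved the median of all genes by -0.11, and 53.3% after median centring). The count was 52, 174, 57 and 197 without DM replicates 7, 10, 11 and 12, 165 without NM replicate 1, 181 with the mean of probe sets, 53 with RNA quality as a covariate and 57 without the arrays above its limit, 55 of them among the 97. The calls of MYH8 (-2.13) and HLA-DPB1 (-1.35) ended with that covariate, without those arrays, without the filter and with only the compared groups, and that of MYH8 with array weights (-1.87). In the 65 fits without 1 sample, the calls of MYH8, HLA-DPB1, AGMAT and MYL5 ended in 15, 13, 4 and 2, and those of macrophage (-0.38 to -0.19), regeneration (-0.25 to -0.12), mast cell (-0.33 to -0.31) and MHC class I genes (0.35 and 0.45) in 24, 6, 3 and 2. Without the filter the calls of cytotoxic (-0.10), macrophage (-0.30), dendritic cell (-0.14) and regeneration genes (-0.23) ended and the T cell median was -0.18. The stricter filter and quantile normalization ended the dendritic (-0.55 and -0.40) and mast cell calls (-0.39 and -0.32), quantile normalization and centring the macrophage call (-0.48 and -0.47) and array weights the regeneration call (-0.25). The mean of probe sets ended the MHC class I (0.36) and unfolded protein response calls (0.36), and the latter median was 0.23 with RNA quality as a covariate. Oxidative phosphorylation genes (-0.03, not called) were called lower under 5 alternatives.

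In IBM against the other diseases, CXCL9 rose furthest (log2 fold change 3.32, SE 0.63, adjusted p = 0.00105, n = 26 IBM arrays), and JCHAIN (3.25, SE 0.59), IGLC1 (2.79, SE 0.65), HLA-DQA1 (2.78, SE 0.59) and the nucleotide sugar receptor P2RY14 (2.35, SE 0.32) rose too. CD8A was 2.16-fold higher (1.11, SE 0.23, adjusted p = 0.00252). The largest falls were in osteopontin, a macrophage and matrix protein encoded by SPP1 (-2.67, SE 0.51), the acute-phase inhibitor SERPINA3 (-1.89, SE 0.41), the metallothionein MT1M (-1.47, SE 0.36), MAFF (-1.42, SE 0.41) and NPTX2 (-1.28, SE 0.32). ISG15 (-0.59, SE 0.39), MX1 (-0.96, SE 0.42), MYH3 (0.17, SE 0.82) and CHRNA1 (0.12, SE 0.37) did not pass.

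Of 14 MHC class I presentation genes, 11 rose (12 within the list) and 3 did not pass. Of 11 class II genes, 9 rose (9 within the list) and 2 did not pass. The list medians of 0.79 (adjusted p = 1.46e-15) and 1.25 (adjusted p = 2.05e-12) held with an estimated correlation (adjusted p = 0.0451 for both). PM was about as high, with list means of 10.36 and 9.43 against 10.26 and 9.59 in IBM. PSMB9 (2.03, SE 0.41), HLA-F (1.15, SE 0.23) and HLA-B (0.88, SE 0.18) led the class I list and HLA-DQB1 (1.94, SE 0.39) and HLA-DPB1 (1.41, SE 0.29) the class II list. T cell genes had a median of 1.19 (adjusted p = 2.39e-06, 0.0757 estimated). Of 6 members, 4 rose (CD2, CD3D, LCK and TRBC1) and 2 did not pass; 4 rose within the list. Cytotoxic effector genes had a median of 0.88 (adjusted p = 1.89e-09, 0.0757 estimated). Among 14 members, 7 rose and 7 did not pass; 11 rose and 1 fell within the list. Plasma cell genes had a median of 1.05 (adjusted p = 1.89e-09, 0.0717 estimated). Of 10 members, 5 rose and 5 did not pass; 7 rose within the list. Interferon-gamma genes had a median of 0.92 (adjusted p = 1.71e-08, 0.0757 estimated). Among 11 members, 4 rose (CXCL9, GBP1, GBP2 and IRF1) and 7 did not pass; 10 rose within the list.

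Medians were also higher in IBM for fast fibre (0.42, adjusted p = 0.0031, 0.505 estimated), oxidative phosphorylation (0.18, adjusted p = 3.04e-06, 0.57 estimated) and glycolysis genes (0.32, adjusted p = 0.000211, 0.505 estimated). They were lower for type I interferon-stimulated (-0.33, adjusted p = 9.42e-05, 0.707 estimated) and immediate-early genes (-0.38, adjusted p = 2.41e-05, 0.0757 estimated). Members past the threshold were 1 of 12 fast fibre members (PVALB), 0 of 37 oxidative phosphorylation members, 0 of 18 glycolysis members, 0 of 30 interferon members and 1 of 15 immediate-early members (MYC), or 2, 0, 1, 4 and 1 within the list. In total 176 genes changed, 122 upward and 54 downward (69.3% higher, against 47.8% after median centring). The count was 394 with array weights and 117 with only the compared groups, and the call of MAFF ended in the latter, without the filter and in 14 of 65 fits without 1 sample. Array weights and the absence of the arrays above the RNA quality limit ended the fast fibre (0.09 and 0.03) and type I calls (-0.32 and -0.32). That absence also gave 0.09 for oxidative phosphorylation and 0.09 for glycolysis genes, and without NM replicate 3 the fast fibre and glycolysis medians were 0.22 and 0.18. Without the filter the T cell and cytotoxic medians were 0.20 and 0.11. Macrophage genes (0.41, not called) were called higher under 4 alternatives.

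In NM against the other diseases, CXCL9 fell furthest, 24.8-fold (log2 fold change -4.63, SE 1.05, adjusted p = 0.00565, n = 6 NM arrays), and PSMB8 (-3.47, SE 0.81), RSAD2 (-3.45, SE 0.86), JCHAIN (-3.40, SE 0.98) and the butyrophilin BTN3A2 (-3.27, SE 0.80) fell too. The largest rises were in the ribosomal protein RPL27A (2.17, SE 0.60), the hair keratin KRT31 (1.77, SE 0.50), the joint lubricant PRG4 (1.76, SE 0.46), DKK3 (1.76, SE 0.47) and DMBT1 (1.72, SE 0.43). ISG15 (-2.23, SE 0.65) and MX1 (-2.66, SE 0.71) were lower, while CD8A (-0.53, SE 0.39), MYH3 (2.47, SE 1.37) and CHRNA1 (0.19, SE 0.62) did not pass. RNA quality differences averaged 3.01 ± 3.28 in NM (SD).

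Of the MHC class I presentation genes, 10 of 14 members fell and 4 did not pass, and 12 fell within the list, with a median of -1.55 (adjusted p = 2.24e-13, 0.174 estimated). The class I light chain B2M (-1.73, SE 0.26), HLA-B (-1.65, SE 0.31) and HLA-F (-2.03, SE 0.39) led them. Of the type I interferon-stimulated genes, 12 of 30 members fell and 18 did not pass, and 20 fell within the list, with a median of -1.36 (adjusted p = 3.68e-13, 0.601 estimated), among them IFI27 (-2.05, SE 0.49), IFIT3 (-2.71, SE 0.66) and PLSCR1 (-1.96, SE 0.48). Interferon-gamma genes had a median of -1.07 (adjusted p = 0.00042, 0.601 estimated). Of 11 members, 4 fell (CXCL10, CXCL9, GBP1 and IRF1) and 7 did not pass; 7 fell within the list. Lower medians were also found for MHC class II presentation (-1.41, adjusted p = 0.0175, 0.788 estimated), plasma cell (-0.91, adjusted p = 0.0134, 0.788 estimated) and glycolysis genes (-0.72, adjusted p = 9e-06, 0.601 estimated). Higher medians were found for matrix (0.76, adjusted p = 0.000506, 0.788 estimated) and regeneration genes (0.58, adjusted p = 0.00179, 0.601 estimated). Members past the threshold were 2 of 11 MHC class II members (HLA-DRA and HLA-DRB1), 2 of 10 plasma cell members (IGKC and JCHAIN), 7 of 18 glycolysis members, 0 of 18 matrix members and 0 of 12 regeneration members, or 4, 5, 12, 0 and 0 within the list.

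In total 290 genes changed, 82 upward and 208 downward (28.3% higher, against 72.3% without the filter, 50.4% after quantile normalization and 53.3% after median centring, where the last pair moved the median of all genes by 0.15 and 0.18). Without the arrays above the RNA quality limit 8 genes changed, all upward and 6 of them among the 290. Of the 18 named genes that had passed, PRG4 kept its call (2.64, SE 0.56). The 17 others lost theirs, with adjusted p from 0.0515 to 0.827, although 12 of them kept at least 75% of their log2 fold change and 15 had an unadjusted p under 0.05. CXCL9 (-4.54, SE 1.14), PSMB8 (-3.44, SE 0.91), RSAD2 (-3.50, SE 1.04), JCHAIN (-3.45, SE 1.11), MX1 (-2.62, SE 0.89) and ISG15 (-2.07, SE 0.79) hardly moved, with a larger SE on 4 NM arrays, while RPL27A (1.19, SE 0.64), BTN3A2 (-2.26, SE 0.86), HLA-B (-1.10, SE 0.31), B2M (-0.87, SE 0.21) and PLSCR1 (-0.88, SE 0.51) fell to 0.55, 0.69, 0.67, 0.50 and 0.45 of their log2 change. The count was 665, 624, 41, 688 and 72 without NM replicates 1, 2, 3, 5 and 6, 578 without NS replicate 13, 66 without NM replicate 3 and NS replicate 13 together, 41 with RNA quality as a covariate, 95 with array weights, 1193 without the filter, 460 after quantile normalization and 181 with only the compared groups. Of the 18 named genes, 7 kept their call with that covariate, 11 with array weights and 9 without NM replicate 3 and NS replicate 13. Leaving out 1 sample ended the calls of 13 of them, 11 without NM replicate 3, and moved PRG4 to 1.12 without NM replicate 1. Without the arrays above the RNA quality limit the glycolysis call ended (-0.07) and the medians were -0.94 for MHC class I, -0.41 for class II and 0.92 for regeneration genes, which stayed called. Without NM replicate 3 and NS replicate 13 they were -0.60 for class II and -0.24 for glycolysis genes, and with array weights -0.78 and -0.33. The mean of probe sets ended the plasma cell call (-0.53) and the absence of the filter the regeneration call (0.42). The class II call ended without NM replicate 1 (-1.35) or 5 (-1.20), with -0.61 without replicate 3, and the plasma cell call without NM replicate 1 (-0.73) or 2 (-0.83). Regeneration genes were at 0.37 and 0.97 without NM replicates 4 and 5, and glycolysis genes at -0.22 and -1.09 without 3 and 5. Cytotoxic genes (-0.55, not called) were called lower under 6 alternatives.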

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

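The tests on RNA quality in NM, on oxidative phosphorylation genes in DM and on blood in IBM and PM were chosen after the results were seen, while the splits of the samples were planned.

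Among 115 values of named genes and gene lists in the groups of 6 and 7 arrays, 12 had an array far from the nearest of the others relative to the group's range. Chance gives such an array in about 1 of 20 groups. NM replicate 3 was the lowest for COX6A2 (log2 7.59, next 11.65), PYGM (3.90, next 10.77) and the means of slow fibre (10.81, next 13.44), oxidative phosphorylation (10.65, next 11.75), glycolysis (8.91, next 11.62) and ubiquitin and autophagy genes (8.32, next 9.11). It was the highest for the B cell mean, which rests on 1 gene (6.5, next 3.84). NM replicate 5 was the lowest for PRUNE2 (4.76, next 9.73), and NM replicate 2 the highest for the Schwann cell mean (5.77, next 5.01). In PM, CACNA2D1 was highest on replicate 3 (5.53, next 3.04), CHRNA1 lowest on replicate 7 (8.13, next 10.39) and CXCL9 lowest on replicate 6 (2.80, next 8.57).

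Of 699 probe sets outside the annotation, 28 were higher than in Normal in DM, 64 in IBM, 61 in NM, 26 in NS and 43 in PM, with 17, 55, 85, 48 and 22 lower.

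The 798 lower genes in NM may come in part from degraded RNA. Leaving out NM replicates 3 and 6, the 2 arrays above the RNA quality limit, left 124 lower genes, against 53 to 1169 (median 678.5) without the 14 other pairs of NM arrays. Replicates 3 and 4 left fewest (53), and replicate 4 has the third highest difference in NM (2.67, just under the limit), and replicates 4 and 6 left 252, which both go with degraded RNA. With replicate 1, 2 or 5, which lie far under the limit, replicate 3 left 329, 222 and 483, replicate 6 left 668, 542 and 769, and replicate 4 left 738, 689 and 870. The glycolysis median per array was lower than in Normal by a difference of -0.52 without all arrays above the limit (SE 0.26, bounds -1.04 to 0.01, two-sided exact permutation p = 0.0103, n = 4 and 11) and of -1.07 with them (SE 0.53, exact permutation p = 0.00108, n = 6 and 12). Whether RNA quality or the disease lowered these genes cannot be told apart, because the bounds reach past 0 while the exact test passes, and because 4 arrays remain.

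The lower oxidative phosphorylation genes in DM moved with other muscle transcripts. Their mean minus that of fast fibre, slow fibre and glycolysis genes on the same array differed from Normal by -0.02 (bounds -0.24 to 0.20, permutation p = 0.86), which is consistent with a fall of muscle fibre transcripts in general as a hypothesis. The other cell types did not all gain alike, since the macrophage mean gained 1.70 more than the endothelial mean (SE 0.30). That restates list results seen before the test was chosen. It cannot decide whether a lower share of muscle RNA lowered these genes. Degraded RNA as the whole cause is argued against, since RNA quality, read from both controls together, differed by 0.07 (SE 0.31) between DM and Normal. The upper bound of that difference, with the steepest bound of the slope on it, allows a change of the list mean of -0.08, against -0.40 seen (upper bound -0.28). A change in the fibres themselves and a displacement of fibres by infiltrating cells both stay open.

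Blood left in the biopsies as the source of the higher T cell genes in IBM and PM is argued against by the erythroid genes. The upper bound of the change of their mean, the larger of the bounds in IBM and PM, was 0.26, while the T cell mean rose by 1.74 (SE 0.25) in IBM and 1.66 (SE 0.54) in PM. Without PM replicate 5, the lowest of PM for these genes, the bound in PM was 0.31 and the T cell rise 1.65 (SE 0.63). T cells within the tissue remain as a hypothesis.

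In 100 splits of the samples drawn for each comparison, the real one included, chance can be excluded for the counts of DM against Normal (718, highest other split 52), IBM (1406, 136), NM (1478, 349) and PM (859, 43), where 1 split, the real one, reached the count. The same holds for IBM against other diseases (176, highest other 16), with 1 split. For NS (755, highest other 1002) 2 splits reached the count. For DM and NM against other diseases 3 (97, highest other 1125) and 4 (290, highest other 1988) did. These lie under 5 in 100, a limit not adjusted over the comparisons, so chance stays possible. The NM count is 41 without NM replicate 3. Some splits in DM and NM called several times the real count. Groups drawn there could mix the diagnoses, and the source of these high counts was not established. In NM against other diseases the 3 other splits that reached the count each had NM replicate 3 or NS replicate 13 in the group of 6, as had 16 of the 96 that did not, while in DM 1 of 2 and 29 of 97 had. For IBM against PM the splits decide nothing, because the real count of 0 is reached by all 100 of them whatever the data (highest other 88).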

How the results depend on the processing

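The fits without NM replicate 3 and NS replicate 13, the 2 arrays that stand apart, and without the 9 arrays above the RNA quality limit were chosen after the data were seen, and the others were planned. No named gene reversed. Of the list medians 2 did, neither called in the main fit: cell cycle genes in IBM against other diseases, 0.16, were called at -0.063 without the filter, and adipocyte genes in NM against other diseases, 0.06, at -0.455 without the arrays above the RNA quality limit. The balance of higher and lower genes turned under some alternatives in all 5 comparisons with Normal and in IBM and NM against other diseases. No paired analysis was possible because the labels give no replicate numbers shared between groups. Signal near the floor limits what can be said of KLRG1 and other dim genes. The variance trend with robust estimation kept all 187 named genes and all 279 list medians on their side of the threshold. The largest losses were 25 named genes without the arrays above the RNA quality limit and 19 with RNA quality as a covariate. Calls were gained too, as for fast fibre genes in PM under 5 alternatives and immediate-early genes in NM under 5 (1.02 with the mean of probe sets to 1.52 without the arrays above the RNA quality limit). MHC class II genes in NM (0.56) gained a call at 1.15 without these arrays. Except where fewer samples or a further threshold is the change itself, the cause was not tested.

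With an added 2-fold threshold the counts were 398 in DM, 621 in IBM, 899 in NM and 363 in NS against Normal, and 52 in DM, 77 in IBM and 183 in NM against other diseases. Array weights gave 1904 in DM, 2745 in IBM and 2235 in PM against Normal, 1 between IBM and PM, and 394 in IBM and 95 in NM against other diseases. Only the compared groups in the fit gave 1199 in DM, 385 in NS and 1434 in PM against Normal, 3 between IBM and PM, and 117 in IBM and 181 in NM against other diseases. RNA quality as a covariate gave 603 in NM and 430 in NS against Normal, and 53 in DM and 41 in NM against other diseases. Without the arrays above the RNA quality limit there were 846 in NM against Normal, and 57 in DM and 8 in NM against other diseases. Median centring gave 2130 in IBM and 1294 in PM against Normal. The mean of probe sets gave 181 in DM against other diseases. In NM against other diseases, no filter gave 1193, quantile normalization 460, and the fit without the 2 arrays that stand apart 66.

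Leaving out each sample in turn gave 493 to 907 genes in DM, 1229 to 1544 in IBM, 889 to 1952 in NM, 403 to 1010 in NS and 515 to 980 in PM against Normal. It gave 0 to 1 between IBM and PM, and 52 to 197 in DM, 131 to 225 in IBM and 41 to 688 in NM against other diseases. Lists called by camera with an estimated correlation numbered 2 in DM, 1 in IBM, 0 in NM, 0 in NS and 0 in PM against Normal, 0 between IBM and PM, and 1 in DM, 2 in IBM and 0 in NM against other diseases. Leaving out 1 sample gained calls of 1 list in DM, 2 in NM, 1 in NS and 3 in PM against Normal, 9 between IBM and PM, and 7 in DM and 5 in NM against other diseases. By fry lists called numbered 2 in NS against Normal, 0 between IBM and PM, and 4 in DM, 7 in IBM and 5 in NM against other diseases.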

Other observations

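The genes described first were picked after their values were seen, whereas the 4 correlations among IBM samples were planned before they were computed. FLT1, a receptor of vascular endothelial growth factor on endothelial cells, fell in each disease group against Normal, with log2 fold changes of -0.81 (SE 0.21) in DM, -0.57 (SE 0.18) in IBM, -0.81 (SE 0.25) in NM, -0.67 (SE 0.20) in NS and -0.69 (SE 0.24) in PM and adjusted p from 0.00609 in DM to 0.0481 in PM, although camera did not call the endothelial list there. The call ended in 12 of 19 fits without 1 sample in PM and without NM replicate 2 in NM (-0.70). GADD45A, a stress gene also induced by denervation, rose in all 5 comparisons with Normal, by 2.72 (SE 0.51) in DM, 3.11 (SE 0.43) in IBM, 3.59 (SE 0.62) in NM, 2.54 (SE 0.49) in NS and 3.44 (SE 0.59) in PM on the log2 scale. The asparagine synthetase gene ASNS rose in DM (3.16, SE 0.53), while its calls in IBM, NM and PM each ended without single samples.

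Parvalbumin, a calcium-binding protein encoded by PVALB and a member of the fast fibre list, rose in IBM (3.23, SE 0.69) while that list had a median of -0.22 there. ERBB3, a neuregulin receptor of Schwann cells, rose in IBM (2.40, SE 0.45), and the myelin gene MBP of the same list fell in IBM (-1.54, SE 0.38) and NM (-2.70, SE 0.54). UBE2B, a ubiquitin-conjugating enzyme, fell in IBM (-0.73, SE 0.19) and NM (-1.32, SE 0.28, -0.88 without NM replicate 3). Calls of PVALB in PM, ERBB3 and UBE2B in NS and MBP in DM ended without single samples. HBB in PM (-2.32, SE 0.61) rests on PM replicate 5: without it the change was -1.04 (SE 0.43, adjusted p = 0.109).

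Among the 26 IBM samples, 4 correlations between list means were computed, with two-sided permutation tests. MHC class I expression was expected to follow the cytotoxic infiltrate, and the means of cytotoxic and MHC class I genes correlated at r = 0.82 (p = 1e-05, the smallest the permutations can give, adjusted p = 4e-05; rho = 0.87, with the same p and adjusted p). The correlation was 0.81 without the 2 samples farthest from the median, 0.85 after RNA quality was taken out and 0.84 within the 23 arrays under its limit. Plasma cell and cytotoxic genes correlated at r = 0.53 (p = 0.00574, adjusted p = 0.0115; rho = 0.49, p = 0.0129, adjusted p = 0.0259), with 0.57 without the 2 farthest samples, 0.52 after RNA quality and 0.51 within its limit, which is in line with both cell types accumulating in the same biopsies. Macrophage and regeneration genes correlated at r = 0.41 (p = 0.0374, adjusted p = 0.0498; rho = 0.34, p = 0.0875, adjusted p = 0.117), with 0.25 without the 2 farthest samples, 0.45 after RNA quality and 0.43 within its limit. It stays undecided, since the rank correlation missed the threshold and r was lower without those 2 samples. Cytotoxic and oxidative phosphorylation genes gave r = -0.17 (p = 0.4, adjusted p = 0.4; rho = -0.30, p = 0.141, adjusted p = 0.141; r = -0.24 without the 2 farthest samples), and a p that misses the threshold does not exclude the relation that was looked for. The infiltrating cells themselves express MHC class I genes, so the correlation of 0.82 may reflect their own transcripts, and the data do not separate them from those of the fibres.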
